A study of Mus musculus with 10 samples.

How the data were processed

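RNA from 10 mouse libraries was measured by sequencing of poly-A RNA prepared with a TruSeq kit that does not mark strand, per the labels' protocols. The labels place 4 libraries in the Ptch group (cerebellum of Ptch heterozygous mice), 3 in the NKP group (medulloblastoma with Nestin-Cre and 1 floxed Kmt2d copy) and 3 in the AKP group (medulloblastoma with Atoh1-Cre and 1 floxed Kmt2d copy). Per the submitters' processing notes, the tools were Trim Galore, STAR and RSEM and the genome build was GRCm38; their versions and the annotation are not given in the sources used here. The deposited table holds 1 value per gene symbol and library, taken here as RSEM expected counts that the authors rounded, since all values are whole numbers and the library totals differ. Rounding before the tests therefore changed no value. RSEM divides reads among near-identical genes by estimation, so values of the hemoglobin genes and of other gene families with close copies are uncertain. Reads of overlapping or antisense genes cannot be told apart without strand.

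The table listed 39769 gene symbols, of which 39754 (99.96%) matched the RefSeq annotation of GRCm38.p6, which supplied gene coordinates. Transcript lengths and GC content came from the GENCODE vM21 transcripts. Library totals ran from 12300430 to 19348991 counts. Genes were kept by edgeR's filterByExpr with the 3 groups, which left 15617 genes. Library sizes were scaled by TMM, and levels are given as CPM on that scale. Group differences were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersion, in 1 fit of all 10 libraries without covariates, at a Benjamini-Hochberg adjusted p below 0.05. Each log2 fold change is given with a standard error (SE), taken as its size divided by the square root of the F statistic. The NKP and AKP groups were each compared with the Ptch group, and the AKP with the NKP group. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

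Before the data were examined, 38 gene lists for pathways, chromatin complexes and cell types were fixed. Lists with at least 5 tested genes were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over 34 lists. A list of sex-linked genes was kept for a check of the labels, and 3 lists had too few tested genes. An estimated correlation for each list was an alternative. The rule for named genes was fixed at the same time. It took Kmt2d and Ptch1 in each comparison, and Ncam2, Atoh1, Gli1, Nes and Kdm6a in the comparisons with Ptch. It added the 4 largest rises and 4 largest falls among genes past the threshold with at least 2-fold change, a mean count of at least 100, groups that did not overlap in CPM and a symbol that is not a clone or predicted name. It also added the 2 members with the smallest p of 8 main lists and 1 member of each other list that passed, limited in the AKP against NKP comparison to members past the threshold. Exceptions to a list's direction could be named as well.

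Alternatives fixed in advance were other scalings (RLE and upper quartile), DESeq2 1.42.0, other filters on low counts, fits of only the 2 groups compared, sex label or age as a covariate, age-matched libraries, the replicate number as a block and each library left out in turn. Those added after seeing the data left out 4 libraries whose Y-linked expression went against the sex label, left out a further library, used Y-linked expression as a covariate, or corrected each library for trends with transcript length and GC content. That correction took each gene's log2 CPM (prior count 1) as its deviation from the gene's mean over the libraries. It fitted lowess trends (span 0.3) of those deviations in each library against the length and then the GC content of the longest annotated transcript, available for 95.6% of the tested genes, and used them as offsets. Age-matching and leaving libraries out left some groups with 1 library, which is then assumed to vary like the others in the fit. Leaving out NKP 2 as well as the 4 libraries against their sex label left NKP 1 as the only NKP library. Y-linked expression entered the covariate as present or absent. It was absent only in Ptch 1 and Ptch 2, so this covariate marks that pair. The mean log2 CPM of the nuclear OXPHOS list per library was also fitted by a linear model on group, with and without the mean of the mitosis list as a covariate. Other splits of the libraries were counted by refitting all 35 or 10 possible splits for each comparison. Comparisons that share controls were set against 40 simulated pairs of unchanged groups.

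The fit was tested on simulated counts for 15617 genes, of which 200 were changed, and the mitosis list was lowered 2-fold as a set. It recovered 61 of 100 genes changed by 2-fold and 87 of 100 changed by 4-fold in the NKP against Ptch design, and 64 and 94 in the AKP against Ptch design. In the AKP against NKP design it recovered 64 and 91. Unchanged genes called numbered 6, 3 and 6. The lowered list was found in each design, and 0 of 33 other lists were called. Simulated genes were drawn independently of each other, so the low preset correlation held by construction. The simulation thus does not show how the tests perform where genes vary together, as they may within these groups. The chi-square per degree of freedom between libraries was lowest at 3.21, for the libraries labelled Ptch 3 and Ptch 4, so no pair agreed within sampling noise. Each library was counted as 1 sample, but this does not show that libraries are independent. Ptch 1 and Ptch 2 had 3.40, as against 24.8 to 26.9 for the other pairs of Ptch libraries. The controls thus form close pairs, which the tests treat as separate samples.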

Results

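Gene-level RNA was measured in 10 mouse libraries from cerebellum or medulloblastoma, a tumour of the cerebellum. By label, 4 libraries came from cerebellum of mice with 1 intact copy of Ptch1, a brake on Sonic hedgehog (SHH) signalling. These form the Ptch group, with Ptch 1 and Ptch 2 at 4 months and Ptch 3 and Ptch 4 at 2 months of age. A further 3 were labelled NKP, for medulloblastoma from Ptch heterozygous mice with Nestin-Cre and 1 floxed copy of Kmt2d, all at 4 months. The remaining 3 were labelled AKP, the same with Atoh1-Cre, with AKP 1 and AKP 2 at 2 months and AKP 3 at 4 months. Total counts were 12300430 in Ptch 1, the lowest, and 19348991 in Ptch 3, the highest.

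Kmt2d, a histone H3 lysine 4 methyltransferase gene on chromosome 15 (98831669 to 98874077, GRCm38.p6), is the floxed gene and was read in each library first. Its level was 68.4, 57.3, 56.3 and 52.6 CPM in the libraries labelled Ptch 1 to 4. It was 33.2, 46.9 and 58.0 CPM in those labelled NKP 1 to 3, and 34.3, 41.3 and 43.6 CPM in those labelled AKP 1 to 3. The library labelled NKP 3 thus lay within the range of the Ptch libraries, against its label, so each direction below that rests on the NKP group includes a library in doubt. A gene-level count may miss the loss of a floxed exon, so Kmt2d checks the labels only in part. Kmt2d did not pass the test in NKP against Ptch (log2 fold change -0.34, SE 0.164, edgeR adjusted p = 0.307) or in AKP against Ptch (-0.56, SE 0.166, adjusted p = 0.0650). Over all alternatives Kmt2d in AKP against Ptch ran from -0.63 to -0.12, the latter after correction for transcript length and GC content (adjusted p = 0.708), with DESeq2 giving the lowest adjusted p, 0.0172. In the same comparison, leaving out NKP 1 or NKP 3 gave an adjusted p of 0.0221 and 0.0393, and a fit of only the AKP and Ptch groups 0.0264. In NKP against Ptch, Kmt2d ran from -0.72 to -0.16 and passed in 0 of 24 alternatives.

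Xist, transcribed from the inactive X chromosome, and 4 Y-linked genes went against the sex label in 4 of 10 libraries. The library labelled Ptch 1, labelled male, had 251 CPM of Xist and 0.385 CPM of the Y-linked genes summed. The libraries labelled Ptch 3, NKP 3 and AKP 3, labelled female, had Y-linked sums of 99.2, 87.1 and 68.4 CPM. The library labelled NKP 2 had Xist at 74.8 CPM and Y-linked genes at 68.4 CPM together. Lower Xist beside Y-linked genes was also seen in AKP 1 (15.0 CPM), NKP 1 (11.9), Ptch 3 (10.2) and AKP 3 (5.38). In Ptch 4, NKP 3 and AKP 2, Xist was at 0.444, 0.438 and 0.433 CPM. The cause was not tested.

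**Figure D1:**
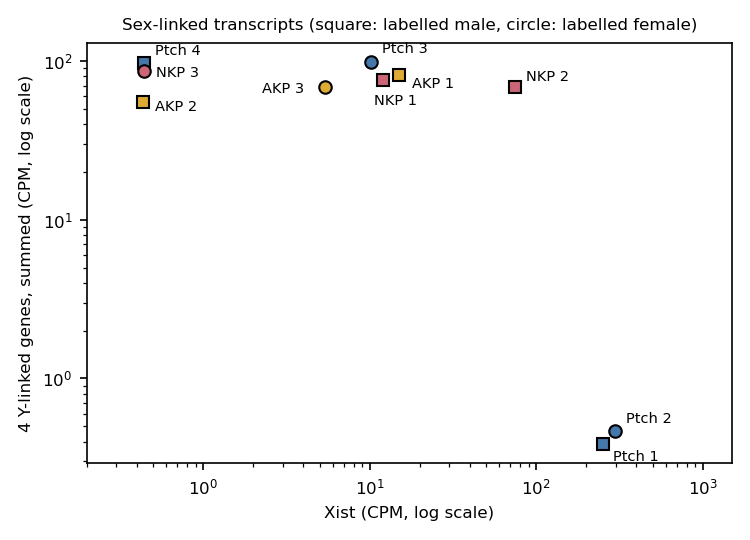
Xist CPM against the summed CPM of 4 Y-linked genes, on log axes, with 1 point per library, squares for libraries labelled male and circles for those labelled female. The library labelled Ptch 1 (male) lies at 251 CPM of Xist and those labelled Ptch 3, NKP 3 and AKP 3 (female) lie between 68.4 and 99.2 CPM of Y-linked RNA.

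Libraries did not group by label. The first principal component held 46.2% of the variance and placed the libraries labelled NKP 1, NKP 2 and AKP 1 at 49.7, 50.7 and 50.3, while Ptch 1 and Ptch 2 lay at -51.0 and -48.3. AKP 2 and AKP 3 lay at -33.6 and -21.7, and NKP 3, Ptch 3 and Ptch 4 at 11.3, -5.30 and -2.03. The proliferation marker Mki67, singled out after its values were seen, was lowest in the same 3 libraries (NKP 1, NKP 2 and AKP 1) and highest in Ptch 1 and Ptch 2. It was 84.1 and 80.4 CPM in Ptch 1 and Ptch 2, 28.8 and 27.3 in Ptch 3 and Ptch 4, 0.654, 0.719 and 11.8 in NKP 1 to 3, and 0.575, 49.1 and 38.8 in AKP 1 to 3. Atoh1, a marker of granule neuron precursors, was at 14.8, 16.4, 6.92 and 5.71 CPM in Ptch 1 to 4, 0, 0.221 and 3.67 in NKP 1 to 3, and 0, 5.77 and 5.45 in AKP 1 to 3. Both genes were thus lowest in 3 libraries labelled medulloblastoma and highest in 2 labelled cerebellum. Whether the tissue labels of these 5 libraries are right stays open, and the folds below compare groups by label. By label the Ptch mice lack an intact copy of Ptch1, a brake on SHH signalling. High levels in their cerebellum therefore need not go against the label. The closest pairs of libraries across groups were NKP 1 and AKP 1, with a chi-square per degree of freedom of 3.42 over genes (correlation of log2 CPM 0.9929), and NKP 3 and Ptch 4, with 3.70 (0.9941). Ptch 1 and Ptch 2 had 3.40, and NKP 3 had 14.3 and 16.0 with NKP 2 and NKP 1.

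**Figure D2:**
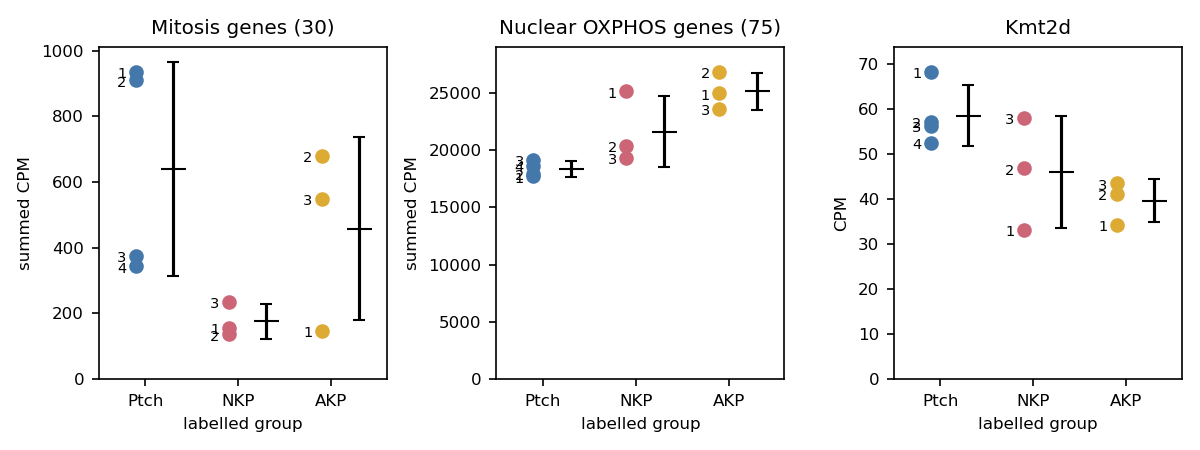
Summed CPM of the mitosis list, summed CPM of the nuclear oxidative phosphorylation list and Kmt2d CPM in each library by labelled group, with replicate numbers as points and black bars for mean ± SD. The mitosis sum runs from 136 CPM in the library labelled NKP 2 to 936 CPM in Ptch 1.

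The NKP against Ptch comparison asks how libraries labelled as tumours with Nestin-Cre and floxed Kmt2d differ from those labelled Ptch cerebellum. Genes of mitosis and DNA replication were lower as lists in the libraries labelled NKP, each with adjusted p = 0.287 with an estimated correlation. Mitosis genes summed to 176 ± 53.1 CPM (SD, n = 3) in NKP and 641 ± 326 CPM (SD, n = 4) in Ptch, with a median log2 fold change of -3.03 and 30 of 30 genes below 0. DNA replication genes summed to 325 ± 62.7 (SD, n = 3) and 789.7 ± 294 CPM (SD, n = 4), with a median of -1.67. Oligodendrocyte, endothelial and red blood cell lists were higher, with medians of 0.50, 0.50 and 0.97. Granule neuron precursor markers (median -1.001) and SHH pathway genes and targets (-0.73) were lower. Each of these 5 lists also had adjusted p = 0.287 with an estimated correlation.

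In NKP against Ptch, camera with the preset correlation gave the mitosis list an adjusted p of 7.99e-19 and the DNA replication list 1.48e-22. The granule neuron precursor and SHH lists had 7.24e-07 and 1.02e-07, and the oligodendrocyte, endothelial and red blood cell lists 9.19e-12, 1.15e-12 and 6.07e-06. With an estimated correlation, each of these 7 lists had adjusted p = 0.287. Adjusted over the list alone, 29 of 30 mitosis, 27 of 30 replication, 5 of 20 precursor and 4 of 18 SHH genes were lower, and 12 of 15 oligodendrocyte, 13 of 15 endothelial and 6 of 6 red blood cell genes higher. No gene passed over all genes by edgeR, where 2660 of 15617 had an unadjusted p under 0.05 and the smallest adjusted p was 0.218. DESeq2 called 410 (76 higher, 334 lower), age as a covariate in edgeR 933, and only the libraries of 4 months 2575. The Ptch libraries of 4 months are Ptch 1 and Ptch 2 alone, the pair highest in Mki67 and Atoh1, so age cannot be told apart from that pair. The edgeR count without a covariate stayed at 0 with each library left out in turn.

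Named genes in NKP against Ptch had the following values, with no call by edgeR over all 10 libraries and no covariate. Atoh1, the transcription factor of granule neuron precursors, was at 1.30 ± 2.06 CPM (SD, n = 3) in NKP and 10.96 ± 5.43 CPM (SD, n = 4) in Ptch, with a log2 fold change of -2.99 (SE 1.32, adjusted p = 0.302). Gli1, a transcriptional target of SHH signalling, was at 13.2 ± 3.65 and 31.6 ± 11.7 CPM (-1.25, SE 0.384, adjusted p = 0.218). The mitotic kinase gene Bub1 was at 0.949 ± 0.638 and 7.60 ± 4.21 CPM (-2.97, SE 0.846, adjusted p = 0.218), and Ttk had -2.85. The SHH genes Ccnd1 and Smo had -0.54 and -0.43, the precursor markers Pax6 and Meis1 -0.30 and -0.67, and the replication gene Pold1 -0.96. Ptch1 had 0.16 (adjusted p = 0.669), Nes -0.74, Ncam2 0.08 and Kdm6a -0.12. Over the 24 alternatives Atoh1 ran from -10.3 to -2.19, Gli1 from -1.68 to -0.71 and Nes from -1.15 to -0.16. Others took both signs: Ptch1 (-0.07 to 0.39), Ncam2 (-0.14 to 0.35) and Kdm6a (-0.38 to 0.11). The oligodendrocyte gene Mag had 0.45, the endothelial gene Ly6c1 0.53 and Alas2, an enzyme gene of heme synthesis, 1.18. In age-matched libraries edgeR called 34 of 42 named genes, among them Gli1, Bub1, Ttk, Ccnd1, Smo, Pax6, Meis1, Pold1, Nes, Ptch1, Mag, Ly6c1 and Alas2. With age as a covariate it called 26, these without Ttk and Ptch1. DESeq2 called 17, with Bub1, Ccnd1, Meis1, Pold1, Mag, Ly6c1 and Alas2 of those above. The age-matched Ptch libraries were Ptch 1 and Ptch 2, the pair highest in Mki67 and Atoh1. Age thus cannot be told apart from that pair in the fits by age.

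Other lists passed in NKP against Ptch, for 27 of 34 in all (15 higher, 12 lower). MYC target and ribosome biogenesis genes (median -0.28, adjusted p = 1.09e-09; Nop58 -0.80), COMPASS genes (-0.23, 5.46e-05; Ash2l -0.45, Kmt2b -0.42), lysine demethylases (-0.18, 0.00107; Phf2 -0.39, Kdm5b -0.36) and the PRC2, HDAC and DNA methylation list (-0.19, 0.00107; Dnmt1 -0.67) were lower. Each had an adjusted p = 0.287 with an estimated correlation. Microglia markers (-0.36, 0.000889; Aif1 -0.88) and immediate early genes (-0.44, 0.000702; Npas4 -0.96) were lower, with adjusted p = 0.327 and 0.306 with an estimated correlation. Mitochondrially encoded OXPHOS (0.39, 1.40e-07; mt-Nd3 0.62) and TCA cycle genes (0.18, 0.000291; Sucla2 0.32) were higher, each with adjusted p = 0.287 with an estimated correlation. Nuclear OXPHOS genes were higher (0.24, 4.46e-18; Cox7b 0.41, Ndufv2 0.34), with adjusted p = 0.306 with an estimated correlation. Glycolysis genes (0.17, 0.00119; Hk2 went the other way at -0.90) were higher, with adjusted p = 0.291 with an estimated correlation. Purkinje cell markers (0.30, 0.000291; Pcp4 0.44) had adjusted p = 0.374 and astrocyte markers (0.11, 0.0117; S100b 0.39) 0.337 with an estimated correlation.

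Several NKP against Ptch list calls rested on single libraries. The choroid plexus list (median 0.42, adjusted p = 0.0195; Kcnj13 0.80) had a median of 0.05 (adjusted p = 0.779) without NKP 2, and adjusted p = 0.147, 0.0572 and 0.0571 without NKP 3, Ptch 1 and Ptch 2. Its median turned to -0.50 without the 4 libraries against their sex label and NKP 2, a fit in which NKP 1 is the only NKP library. The mature granule neuron list (0.19, adjusted p = 0.0117; Kcnk1 0.24, Vsnl1 0.29) had 0.194 without NKP 1, and the coactivator list (-0.13, 0.0193; Smarca4 -0.35) 0.244 without NKP 1. The interneuron list (0.20, 0.0189; Pvalb 0.56) had 0.169 without NKP 3 and 0.0571 without Ptch 2. The meningeal list (0.29, 0.00119; Slc6a13 0.67) had 0.0702 without NKP 2. The synaptic list (0.09, 0.0452; Vamp1 0.38, Cplx1 0.28) had 0.456, 0.193 and 0.180 without NKP 3, Ptch 1 and Ptch 2. The hypoxia list (0.23, 0.0334; Bnip3 0.41) had 0.161, 0.0613, 0.0582 and 0.0508 without NKP 2, NKP 3, Ptch 3 and Ptch 4. The list of CDK inhibitors and p53 targets (-0.10, 0.0498; Cdkn2a -2.74) had 0.125 and 0.157 without NKP 1 and NKP 3, 0.0516, 0.0599 and 0.0537 without Ptch 1, 2 and 3, and 0.0592 without AKP 2. With an estimated correlation these 8 lists had adjusted p = 0.479, 0.493, 0.352, 0.374, 0.291, 0.542, 0.287 and 0.347 in that order. After the length and GC correction the coactivator, hypoxia and CDK inhibitor calls ended (adjusted p = 0.138, 0.0507 and 0.0567). With Y-linked expression as a covariate the choroid plexus (median 0.18), mature granule neuron (0.08), interneuron (0.03), synaptic (-0.01) and CDK inhibitor calls (-0.04) ended, and in age-matched libraries the coactivator, hypoxia and meningeal calls (adjusted p = 0.291, 0.176 and 0.0989).

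List medians in NKP against Ptch also moved by over 1.5 times in fits where the call held, with 1 library left out or under other alternatives. Some of these lists lost their calls in other fits, as given above. Red blood cell genes summed to 2486 and 1245 CPM in NKP 1 and NKP 2 but 782.5 CPM in NKP 3, within the Ptch libraries (710.9 to 816.5 CPM). Without NKP 1 the medians were 0.46 for red blood cell, 0.27 for oligodendrocyte, 0.20 for Purkinje cell, 0.10 for nuclear OXPHOS and -0.12 for demethylase genes. The interneuron median was 0.31 without Ptch 3 and that of CDK inhibitors -0.04 without Ptch 4. Without the 4 libraries against their sex label and NKP 2, NKP 1 is the only NKP library. Red blood cell, oligodendrocyte and nuclear OXPHOS medians were then 1.67, 0.90 and 0.51, and the microglia median was -0.40. Without those 5 libraries, Purkinje cell, mature granule neuron, astrocyte and glycolysis medians were 0.57, 0.35, 0.19 and 0.26, and COMPASS, demethylase and coactivator medians -0.36, -0.34 and -0.29. With Y-linked expression as a covariate, DNA replication, precursor, SHH and endothelial medians were -0.96, -0.33, -0.42 and 0.32, and those of PRC2, demethylase, Purkinje cell and hypoxia genes -0.06, -0.10, 0.18 and 0.14. That covariate marks Ptch 1 and Ptch 2, the only libraries without Y-linked expression. Mitochondrially encoded OXPHOS genes had a median of 0.14 with that covariate, 0.20 after the length and GC correction, 0.62 with age as a covariate and 0.73 in age-matched libraries. Age-matched medians were also higher for choroid plexus (0.72), Purkinje cell (0.48), interneuron (0.40) and synaptic genes (0.20), and lower for PRC2 genes (-0.30). With age as a covariate, interneuron, mature granule neuron, astrocyte, synaptic and CDK inhibitor medians were 0.39, 0.29, 0.16, 0.15 and -0.17.

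The AKP against Ptch comparison asks the same of tumours with Atoh1-Cre. Nuclear genes for subunits of oxidative phosphorylation (OXPHOS), the respiratory chain and ATP synthase, were higher in the libraries labelled AKP, with adjusted p = 0.329 with an estimated correlation. The list summed to 25110 ± 1641 CPM (SD, n = 3) in AKP and 18340 ± 668 CPM (SD, n = 4) in Ptch, with a median log2 fold change of 0.52 and 74 of 75 genes above 0. Of these, 56 rose over all genes tested, and 70 when adjusted over the list alone. Red blood cell genes (median 1.23) and oligodendrocyte markers (0.46) were higher too, and lists of chromatin enzymes were lower: COMPASS genes (-0.36), lysine demethylases (-0.33) and H3K27 acetylation coactivators (-0.34). With an estimated correlation these 5 lists had adjusted p = 0.329, 0.509, 0.448, 0.329 and 0.329 in that order.

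In AKP against Ptch, edgeR called 887 of 15617 genes (528 higher, 359 lower), of which 57 changed at least 2-fold (37 higher, 20 lower). Upper quartile scaling gave 741 higher of 994, or 74.55%, as against 59.53% here. The count was 0 without AKP 3, 1 without AKP 2, Ptch 1 or Ptch 2, 183 without Ptch 4, 321 without Ptch 3, 553 without NKP 2 and 1459 without AKP 1. It was 1859 by DESeq2, 231 with sex label and 3 with Y-linked expression as a covariate, 16 after correction for transcript length and GC content, and 0 in age-matched libraries or without the 4 libraries against their sex label. Y-linked expression was absent only in Ptch 1 and Ptch 2, so that covariate cannot be told apart from this pair.

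The largest rises in AKP against Ptch were in Lamp5, a membrane protein gene of neurons (chromosome 2, 136052025 to 136069917), and Spp1, which encodes osteopontin (chromosome 5, 104435111 to 104441053). Lamp5 was at 34.2 ± 14.6 CPM (SD, n = 3) in AKP and 6.59 ± 1.03 CPM (SD, n = 4) in Ptch (log2 fold change 2.38, SE 0.285, adjusted p = 0.0209). Per library, Lamp5 was at 17.6, 44.8 and 40.2 CPM in AKP 1 to 3. AKP 2 and AKP 3 also had the highest sums of brainstem markers, given below. Spp1 was at 84.9 ± 18.8 and 27.01 ± 8.58 CPM (1.65, SE 0.269, adjusted p = 0.0211). Hemoglobin genes rose next, Hbb-bs by 1.44 (SE 0.326, adjusted p = 0.0423) and Hba-a1 by 1.27 (SE 0.305, adjusted p = 0.0477), with levels uncertain because of their near-identical copies. The largest fall was in Nptxr, a neuronal pentraxin receptor gene (chromosome 15, 79786351 to 79804709), at 9.61 ± 3.36 and 38.8 ± 2.31 CPM (-2.02, SE 0.200, adjusted p = 0.00371). Ago2, an effector of microRNA silencing, had -1.42 (SE 0.213), Ddi2 -1.37 (SE 0.255) and Tnks -1.14 (SE 0.204), each with adjusted p = 0.0209. The calls were lost in 5 of 24 alternatives for Nptxr, 9 for Lamp5, 10 each for Spp1, Ago2, Ddi2 and Tnks and 17 each for Hbb-bs and Hba-a1, with 0 reversed.

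For the OXPHOS list in AKP against Ptch, camera gave an adjusted p of 9.29e-53, and adjusted p = 0.329 with an estimated correlation. Ndufb5, of complex I, rose from 159 ± 3.23 to 239.8 ± 19.1 CPM (0.59, SE 0.0944, adjusted p = 0.0209), and Atp5l, of ATP synthase, by 0.69 (SE 0.114, adjusted p = 0.0209). OXPHOS transcripts are short, with a median of 1092 nt as against 3372 nt for all genes. Across genes, which are not independent replicates, log2 fold change and transcript length had a Spearman rho of -0.476. After correction for length and GC content the list's median was 0.21 (adjusted p = 1.71e-23) and 1 of its 75 genes passed. Per library, the mean log2 CPM of the list was higher in AKP by 0.49 (SE 0.103, 95% interval 0.24 to 0.73) before and by 0.24 (SE 0.0643, 0.08 to 0.39) after the correction.

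Red blood cell genes in AKP against Ptch (3 of 6 higher over all genes, 5 adjusted over the list alone; Alas2 1.19) had adjusted p = 6.42e-07, and 0.329 with an estimated correlation. Oligodendrocyte markers (1 of 15; 11 adjusted over the list alone; Mobp 0.56) had 1.89e-07, and adjusted p = 0.509 with an estimated correlation. Endothelial markers (median 0.35; 2 of 15; 5 adjusted over the list alone; Ly6c1 0.69) had 6.01e-05, and adjusted p = 0.509 with an estimated correlation. COMPASS genes (3 of 18 lower; 11 lower and 1 higher adjusted over the list alone) had 1.69e-05, and adjusted p = 0.448 with an estimated correlation. Ncoa6 (-0.49) and Kmt2c (-0.41) fell among them. Lysine demethylases (3 of 22 lower; 12 adjusted over the list alone; Kdm5c -0.61, Jmjd1c -0.40) had 4.69e-06 and coactivators (2 of 14; 9 adjusted over the list alone; Med12 -0.69) 8.56e-06, each with adjusted p = 0.329 with an estimated correlation. After the length and GC correction the COMPASS and demethylase medians were -0.16 and -0.17, both still past the threshold, and the coactivator call ended (-0.10, adjusted p = 0.0748). With Y-linked expression as a covariate the endothelial call ended (0.14, adjusted p = 0.0538).

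The remaining 11 list calls in AKP against Ptch, for 18 of 34 in all (8 higher, 10 lower), each ended without at least 1 library. Mitosis (median -0.64, adjusted p = 0.0347; Cenpe -1.20 and Bub3 0.14, neither passing), DNA replication (-0.53, 0.00485; Mcm4 -0.49) and granule neuron precursor lists (-0.40, 0.0347; Barhl2 -0.47, Zic5 -0.74) had 0 genes past the threshold. Without AKP 1 they had adjusted p = 0.772, 0.772 and 0.698. Without Ptch 1 they had 0.145, 0.0505 and 0.0716, and without Ptch 2 0.142, 0.0596 and 0.0793. SHH pathway genes (-0.42, 0.00215; Boc fell by 0.44, Ccnd1 -0.42 did not pass), glycolysis (0.16, 0.00648; Pgk1 0.39), mitochondrially encoded OXPHOS (0.32, 0.00201; mt-Nd3 0.85) and TCA cycle genes (0.15, 0.0204; Suclg1 0.36) had 0.108, 0.0691, 0.148 and 0.176 without AKP 1, and TCA cycle genes 0.0658 without Ptch 2. The PRC2, HDAC and DNA methylation list (-0.19, 0.0169; Dnmt1 -0.73) had 0.125, 0.0533 and 0.0658 without AKP 1, Ptch 1 and Ptch 2. Neural cell adhesion genes (-0.18, 0.00440; L1cam -0.53) had 0.0793 without AKP 2. Synaptic genes (-0.15, 0.0116; Bsn fell by 0.49 and Vamp1 rose by 0.54) had 0.170, 0.0660 and 0.0828 without AKP 2, Ptch 3 and Ptch 4. Antigen presentation genes (0.37, 0.0416; Cd74 0.61, not passing) had 0.496 and 0.135 without AKP 2 and AKP 3, 0.114, 0.0985 and 0.0501 without NKP 1 to 3, and 0.0533, 0.0808 and 0.0526 without Ptch 1, 2 and 4. With an estimated correlation these lists had adjusted p = 0.838, 0.817, 0.638, 0.509, 0.509, 0.638, 0.629, 0.509, 0.509, 0.689 and 0.570 in that order.

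Other alternatives ended these 11 calls in AKP against Ptch too. In age-matched libraries the mitosis median was 0.10 (adjusted p = 0.319), DNA replication -0.00 (0.350) and granule neuron precursor markers -0.04 (0.156). With age as a covariate, mitosis (-0.28, 0.174), precursor (-0.15, 0.0891) and antigen presentation calls (0.36, 0.0594) ended, as did the mitosis call with sex label as a covariate (-0.58, 0.0533). The synaptic call ended with a replicate block (-0.13, 0.0528), and antigen presentation had 0.0565 in a fit of only these groups, 0.0511 without a filter and 0.0516 with upper quartile scaling. Mitochondrially encoded OXPHOS (0.18, 0.319), TCA cycle (0.08, 0.200), PRC2 (-0.10, 0.319), glycolysis (0.16, 0.0619) and antigen presentation genes (0.23, 0.239) did not pass in age-matched libraries either. With Y-linked expression, absent only in Ptch 1 and Ptch 2, as a covariate the mitosis, replication and precursor medians were 0.36, 0.14 and 0.03 (adjusted p = 0.872, 0.927 and 0.390). The SHH, glycolysis, TCA cycle, mitochondrially encoded OXPHOS, PRC2 and antigen presentation calls ended as well (0.0538, 0.0538, 0.183, 0.582, 0.327 and 0.147). After the length and GC correction mitochondrially encoded OXPHOS genes turned to -0.08 (adjusted p = 0.0971), and TCA cycle (0.07, 0.0920), adhesion (-0.07, 0.297), synaptic (-0.04, 0.863), PRC2 (-0.10, 0.267), precursor (-0.26, 0.0634) and antigen presentation calls (0.33, 0.375) ended. Medians that moved by over 1.5 times with the call kept were -1.12, -0.89 and -0.60 for mitosis, replication and precursor genes without AKP 2. They were -0.33 for adhesion, -0.25 for synaptic and 0.23 for endothelial genes without AKP 1, and 0.52 for mitochondrially encoded OXPHOS without Ptch 4. With a replicate block, mitosis, replication, precursor and mitochondrially encoded OXPHOS medians were -1.25, -0.81, -0.67 and 0.53. Age-matched medians were -0.30 for adhesion, -0.27 for synaptic and 0.19 for endothelial genes, adhesion and synaptic genes had -0.29 and -0.27 with Y-linked expression as a covariate, and replication genes -0.33 with age as a covariate.

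The single genes said to have risen or fallen within lists in AKP against Ptch lost their calls in part of the 24 alternatives. Calls were lost in 9 for Ndufb5 and Vamp1, 10 for Atp5l, mt-Nd3, Ly6c1, Kdm5c and L1cam, 11 for Alas2 and Med12, 12 for Ncoa6 and Dnmt1, 13 for Kmt2c, Bsn, Boc and Pgk1, 14 for Jmjd1c and Mobp and 16 for Suclg1. After the length and GC correction Kmt2c had -0.07 (adjusted p = 0.692) and Bsn -0.08 (0.559), mt-Nd3 0.14, Ly6c1 0.35, Pgk1 0.23, Ncoa6 -0.28 and Jmjd1c -0.22. With Y-linked expression as a covariate Boc had -0.26 and Dnmt1 -0.42. Calls were gained by Barhl2 in 5 alternatives, Kdm6a in 2 and Ccnd1, Zic5, Ptch1, Fat2 and Cd74 in 1 each.

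Genes fixed in advance that did not pass in AKP against Ptch were Ptch1 (-0.33, adjusted p = 0.268), Atoh1 (-1.53, 0.478), Gli1 (-0.62, 0.345), Nes (-0.43, 0.322), Ncam2 (-0.28, 0.565) and Kdm6a (-0.73, 0.0704). The mature granule neuron markers Fat2 (-0.34) and Calb2 (0.40) did not pass either, in a list with a median of -0.08 (adjusted p = 0.489).

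**Figure D3:**
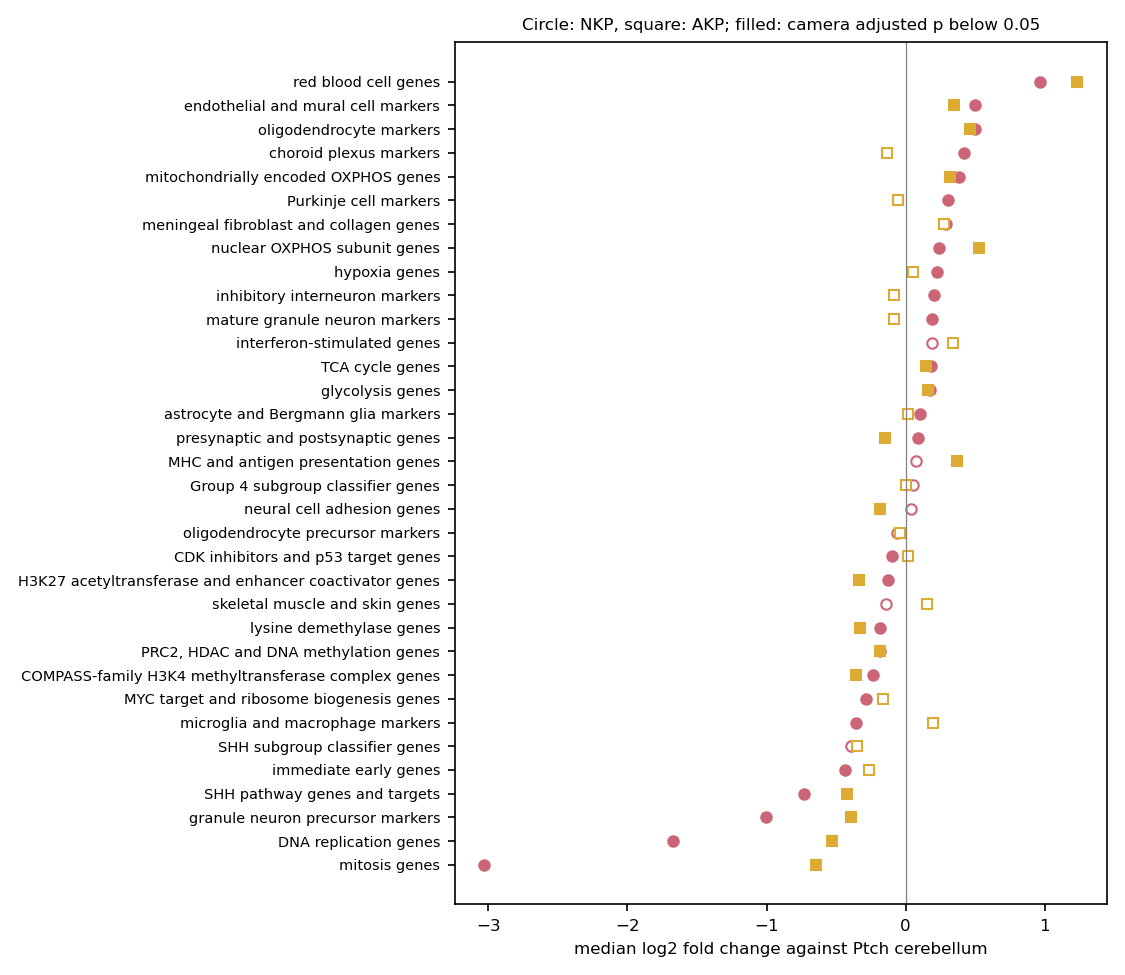
Median log2 fold change of 34 gene lists in the libraries labelled NKP (circles) and AKP (squares) against Ptch, filled where the camera adjusted p is below 0.05. The mitosis list has a median of -3.03 in NKP and -0.64 in AKP, and the nuclear OXPHOS list 0.24 and 0.52.

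The AKP against NKP comparison tests the difference between the tumour groups itself. Mitosis genes were higher in the libraries labelled AKP (adjusted p = 0.574 with an estimated correlation), with a median log2 fold change of 2.35 and sums of 458 ± 278 CPM (SD, n = 3) in AKP and 176 ± 53.1 CPM (SD, n = 3) in NKP. The spread within AKP was wide, with mitosis sums of 146 CPM in AKP 1, 679 in AKP 2 and 549 in AKP 3. Microglia markers likewise summed to 304.2 CPM in AKP 1, within the NKP libraries (295 to 309.4 CPM), and to 608.4 and 495.4 CPM in AKP 2 and AKP 3. DNA replication (1.084), granule neuron precursor (0.80), microglia (0.59) and nuclear OXPHOS lists (0.27) were higher, and choroid plexus (-0.74), Purkinje cell (-0.37) and synaptic lists (-0.23) lower, each with adjusted p = 0.574 with an estimated correlation. Nptxr fell by 1.73 (SE 0.208, edgeR adjusted p = 0.0292), at 9.61 ± 3.36 CPM in AKP and 31.8 ± 4.64 CPM in NKP, and was the 1 gene called.

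In AKP against NKP, 2633 genes had an unadjusted p under 0.05 by edgeR, and DESeq2 called 234 (156 higher, 78 lower). The count was 1364 without AKP 1 and 0 without Ptch 1, 2, 3 or 4, NKP 1, 2 or 3, or AKP 3, and the call of Nptxr was lost in 14 of 23 alternatives. It was 419 with libraries of 4 months alone, where AKP 3 stands alone. Kmt2d (-0.22, SE 0.176, adjusted p = 0.535) and Ptch1 (-0.49, SE 0.187, adjusted p = 0.248) did not pass, and Kmt2d ran from -0.40 to 0.18 over the alternatives.

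Camera called 16 of 34 lists in AKP against NKP (7 higher, 9 lower), each with adjusted p = 0.574 with an estimated correlation. Mitosis and DNA replication genes had adjusted p = 6.05e-10 and 1.29e-09, microglia markers 1.92e-05 (7 of 16 higher adjusted over the list alone) and nuclear OXPHOS genes 1.46e-17. After the length and GC correction the OXPHOS median was 0.01 (adjusted p = 0.0970). It was 0.05 without the 4 libraries against their sex label and NKP 2, where NKP 1 is the only NKP library. MYC target genes (0.21) had 0.000711, Purkinje cell markers 0.000109, interneuron markers (-0.29) 0.00438, synaptic genes 1.11e-06 and adhesion genes (-0.24) 0.000711. The correction lowered the synaptic median to -0.09 (adjusted p = 0.00532) and ended the adhesion call (-0.11, 0.0666), and the interneuron call ended without the 4 libraries against their sex label (-0.16, 0.109). Choroid plexus markers (adjusted p = 0.00182) had a median of -0.28 (0.166) without NKP 2, 0.0578 without AKP 1 and 0.0652 in age-matched libraries. Their median turned to 0.17 without the 4 libraries against their sex label and NKP 2, with NKP 1 as the only NKP library. Granule neuron precursor markers (0.0334) had 0.0886, 0.227, 0.162 and 0.125 without AKP 2, AKP 3, NKP 1 and NKP 2. CDK inhibitors and p53 targets (0.33, 0.00669) had 0.0670 without NKP 1, and mature granule neuron markers (-0.26, 0.00125) 0.0831 and 0.125 without AKP 2 and NKP 1. Coactivators (-0.19, 0.00438) had 0.0713 without NKP 3, and lysine demethylases (-0.16, 0.0340) 0.123, 0.125 and 0.126 without AKP 1, NKP 2 and NKP 3. After the length and GC correction they had medians of -0.05 and -0.01 (adjusted p = 0.668 each), and astrocyte markers -0.12 (0.0970). Astrocyte markers (-0.12, 0.0490) had 0.159, 0.243, 0.170 and 0.111 without AKP 2, AKP 3, NKP 1 and NKP 2, and 0.0648, 0.0609, 0.0554 and 0.0567 without Ptch 1 to 4.

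List medians in AKP against NKP also moved by over 1.5 times in fits where the call held, with 1 library left out or under other alternatives. Some of these lists lost their calls in other fits, as given above. Without AKP 1 the medians were -0.67 for Purkinje cell, -0.50 for mature granule neuron, -0.46 for interneuron, -0.36 for adhesion, -0.23 for astrocyte, 0.50 for CDK inhibitor and 0.32 for MYC target genes. Without AKP 2 they were 0.37 for microglia, 0.09 for MYC target, -0.17 for Purkinje cell, -0.13 for synaptic and -0.13 for adhesion genes. The mitosis median was 3.69 and the interneuron median -0.18 without NKP 3, and the OXPHOS and coactivator medians were 0.43 and -0.28 without NKP 1. With age as a covariate, CDK inhibitor, MYC target, Purkinje cell, interneuron and astrocyte medians were 0.57, 0.37, -0.56, -0.47 and -0.20. Age-matched medians were 0.165 for OXPHOS, -0.42 for mature granule neuron and -0.24 for astrocyte genes. The interneuron median was -0.19 after the length and GC correction. The synaptic median was -0.13 without the 4 libraries against their sex label and NKP 2, where NKP 1 is the only NKP library.

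No gene passed by edgeR in the same direction in both comparisons with Ptch. This overlap of 0, and the 0 for independent lists, were fixed, since edgeR called 0 genes in NKP against Ptch. They say nothing about shared change. Over 40 simulated pairs of unchanged groups with the same controls the mean overlap was 0.025. DESeq2 gave an overlap of 115 genes and age as a covariate 117. The simulated pairs were fitted by edgeR without covariates, so they give no chance overlap for these counts. Both counts rest on shared Ptch libraries and do not show shared change. Across genes, which are not independent replicates, the log2 fold changes of NKP and AKP against Ptch had a correlation of 0.482, as against a simulated mean of 0.422 and a highest of 0.483. Their covariance was 0.104 against a simulated mean of 0.0429, a difference of 0.0613, and a simulated highest of 0.0516. The simulated genes were drawn independently of each other, without the close pairs of Ptch libraries. With the controls split, NKP against Ptch 1 and 2 and AKP against Ptch 3 and 4 had a correlation of -0.08 and a covariance of -0.025, with 1973 and 3 genes called and an overlap of 0 (0.204 for independent lists). The reverse split gave a correlation of 0.385 and a covariance of 0.0872, with 0 and 1554 genes called. Its overlap of 0 was fixed in the same way.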

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

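The tests of exchanged names, of wrong labels on single libraries and of fewer proliferating cells, the means of the OXPHOS list per library, the counts of list calls over other splits, and the length and GC correction as an alternative were chosen after results had been seen.

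Nptxr differed between the tumour groups, at -1.73 (log2) in AKP against NKP. By the test of the difference itself, the median log2 fold changes in AKP against NKP were 2.35 for mitosis, 1.084 for DNA replication, 0.80 for granule neuron precursor, 0.59 for microglia, 0.33 for CDK inhibitor and p53 target, 0.27 for nuclear OXPHOS and 0.21 for MYC target genes. They were -0.74 for choroid plexus, -0.37 for Purkinje cell, -0.29 for interneuron, -0.26 for mature granule neuron, -0.24 for adhesion, -0.23 for synaptic, -0.19 for coactivator, -0.16 for demethylase and -0.12 for astrocyte genes. Each of these 16 lists had adjusted p = 0.574 with an estimated correlation. After the length and GC correction the OXPHOS, coactivator, demethylase, adhesion and astrocyte calls ended, the first 3 with medians of 0.01, -0.05 and -0.01. The mitosis and microglia sums of AKP 1 lay within those of the NKP libraries. Of 73 values checked for a single library far from the others of the Ptch group, 0 stood apart. The Ptch libraries form close pairs, so each has a near neighbour and such a check can hardly flag any of them. The 0 thus does not show that the Ptch libraries are alike. Sex-linked genes, outside the main comparisons, stood against the label with Xist at 251 CPM in Ptch 1 (labelled male) and Y-linked sums of 99.15 CPM in Ptch 3, 87.06 in NKP 3 and 68.39 in AKP 3 (labelled female).

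Mitosis genes were lower in the libraries labelled NKP, a tumour group, than in those labelled Ptch cerebellum, with a median of -3.03 (adjusted p = 0.287 with an estimated correlation). Library scaling as the cause is argued against, since the median was -2.998 at the highest under the other scalings. Library names exchanged among these 10 libraries cannot be told apart from a group difference. Of 33 exchanges between groups, 2 (Ptch 1 with NKP 3 or AKP 3) lower the libraries against their sex label, as wrong sex entries alone would too. With Y-linked expression in 8 libraries and 6 labelled male, no exchange of names can leave fewer than 2 libraries against their label. Exchanged names alone thus cannot account for the sex pattern. In expression, NKP 3 lay nearer to Ptch 4 (chi-square per degree of freedom 3.70) than to NKP 1 or NKP 2 (16.0 and 14.3). Wrong labels on single libraries, of tissue or genotype, remain open too, with Y-linked expression against the sex label in 4 libraries, Mki67 at 84.1 and 80.4 CPM in Ptch 1 and Ptch 2, labelled cerebellum, and 0.719 CPM or less in NKP 1, NKP 2 and AKP 1, labelled medulloblastoma. A wrong sex entry need not mean a wrong tissue or genotype, and a difference between Kmt2d genotypes and the tumour content of each sample also stay open and were not tested.

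Nuclear OXPHOS genes were higher in the libraries labelled AKP than in Ptch, with a median of 0.52 (adjusted p = 0.329 with an estimated correlation) and, per library, a mean log2 CPM higher by 0.49 (95% interval 0.24 to 0.73). Removing each library's trend with transcript length and GC content lowered the median to 0.21 (0.2054, below 0.2624, which is 0.5 of the uncorrected value), the calls over all genes from 887 to 16 and those in the list from 56 to 1 of 75. A length trend may thus lie behind at least part of the rise. The mean per library was still higher by 0.24 (0.08 to 0.39) after the correction and by 0.21 (0.02 to 0.40) without AKP 1, the lowest with any library left out. Whether length is the whole cause cannot be told from this. OXPHOS transcripts are short, and across genes a Spearman rho of -0.0359 with length was left after the correction. Fewer proliferating cells as the whole cause is argued against, since with the mitosis genes as a covariate the mean was higher by 0.47 (0.4652, interval 0.18 to 0.75) before and 0.19 (0.06 to 0.33) after the correction, though after it the interval reached 0 without AKP 2 (0.15, -0.02 to 0.32). The AKP genotype as a cause was not tested apart from these.

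Over other splits of the same libraries, the 887 genes of AKP against Ptch were reached by 1 of 35 splits, the real one. That is the smallest share 35 splits can give. It lies under 0.05, but several such counts were made, so chance is not excluded. The highest other split gave 698, with Ptch 3, Ptch 4 and AKP 1 together. The 887 still rest on single libraries, with 0 genes without AKP 3, 1 without AKP 2, Ptch 1 or Ptch 2, 183 without Ptch 4, 321 without Ptch 3, 553 without NKP 2 and 1459 without AKP 1. For NKP against Ptch the real count is 0, which all 35 of 35 splits reach by construction (highest other 2), so this count says nothing about chance. The 27 lists of NKP against Ptch at the preset correlation were reached by 1 of 35 (highest other 24). This is again the smallest share possible, which does not exclude chance. With an estimated correlation 0 of the 34 lists passed (smallest adjusted p = 0.287), and the count was 22 without NKP 3 or without the 4 libraries against their sex label. The 18 lists of AKP against Ptch were reached by 11 of 35 (highest other 21), so chance cannot be excluded, and 0 passed with an estimated correlation. For AKP against NKP, 10 splits are too few for a share under 0.05: 2 gave as many genes as the real 1 (highest other 49) and 4 as many lists as the real 16 (highest other 21).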

How the results depend on the processing

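The length and GC correction, Y-linked expression as a covariate and the fits without libraries against their sex label were chosen after seeing the data. Genes called in NKP against Ptch (0) were 410 by DESeq2, 933 with age as a covariate and 2575 in age-matched libraries. Genes called in AKP against Ptch (887) were 1859 by DESeq2, 231 with sex label as a covariate, 0 in age-matched libraries, 0 without the 4 libraries against their sex label and 0 without those and NKP 2, 16 after the length and GC correction (15 of them among the 887) and 3 with Y-linked expression as a covariate. Genes called in AKP against NKP (1) were 234 by DESeq2, 419 in age-matched libraries, and 0 in a fit of only these groups, with sex label or age as a covariate and without the libraries against their sex label, with or without NKP 2. Genes shared by both comparisons with Ptch (0, fixed since none was called in NKP against Ptch) were 115 by DESeq2 and 117 with age as a covariate, with no chance overlap simulated for these fits. The Ptch libraries of 4 months are Ptch 1 and Ptch 2, the pair highest in Mki67 and Atoh1. Fits by age thus do not set age apart from that pair, and the covariate of Y-linked expression, absent only there, marks the same pair. Lists called numbered 0 with an estimated correlation in each comparison, as against 27, 18 and 16, and in AKP against Ptch 11 in age-matched libraries and 10 with Y-linked expression as a covariate. Kmt2d in AKP against Ptch (-0.56) passed by DESeq2 (-0.560) and in a fit of only these groups (-0.554), and was -0.12 after the length and GC correction (adjusted p = 0.708). The cause was not tested, except that leaving out libraries lowers the number of samples.

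With each library left out in turn, counts ran from 0 to 0 in NKP against Ptch, 0 to 1459 in AKP against Ptch (0 without AKP 3, 1459 without AKP 1) and 0 to 1364 in AKP against NKP (1364 without AKP 1). Lists ran from 22 to 27, 12 to 18 and 12 to 19. Kmt2d in AKP against Ptch ran from -0.63 (without AKP 3) to -0.47 (without AKP 1), and over all alternatives from -0.63 to -0.12. With a replicate block, which takes libraries with the same number as pairs, 0 genes were called in each comparison, and 26, 20 and 16 lists. The numbers do not pair the samples, since deviations from the group means correlated over 0.1 in 3 of 9 same-number pairs (-0.335 to 0.341), and not every library correlated best with its own number (AKP 1 did so with Ptch 4, at 0.383). Of 2036 values of named genes over alternatives, 1634 kept their side of the threshold (13 of them with the other sign, passing in neither fit), 312 lost a call, 90 gained one and 0 reversed. A further 3 had no adjusted p by DESeq2. Low genes such as Cdkn2a, at 0.165 CPM in NKP, are limited by depth.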

Other observations

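The test of tissue from outside the cerebellum was set before its result was seen, though after Hoxb5 and Slc18a3 had been noticed. The libraries and genes below were singled out after their values were seen. Pituitary hormone genes summed to 88.8 CPM in the library labelled NKP 2 (Gh 36.2, Prl 39.6), 33.0 in AKP 1 and 29.1 in NKP 1, and to 13.1 CPM or less in the other libraries. Ttr, abundant in choroid plexus, was at 3832 CPM in NKP 2.

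Lists with too few tested genes had medians, in NKP and AKP against Ptch, of 0.18 and -0.18 (WNT subgroup classifier), -0.16 and -0.21 (Group 3 classifier) and 0.51 and 0.24 (lymphocyte markers). Of these, lymphocyte markers in NKP had a mean of -0.55, and the Group 3 classifier in AKP a mean of 0.01, against the sign of the median. Median, mean and test also differed in sign for oligodendrocyte precursor markers (-0.04, -0.07, test higher) and the Group 4 classifier (0.00, 0.02, test lower) in AKP against Ptch, and for the PRC2 list (-0.01, 0.06, test higher), the Group 4 classifier (-0.06, 0.01, test lower) and hypoxia genes (0.06, 0.02, test lower) in AKP against NKP, none of which passed. The SHH subgroup classifier (-0.40 in NKP and -0.35 in AKP against Ptch, adjusted p = 0.140 and 0.528) did not pass.

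Hoxb5 (2.09 and 2.06 CPM) and Slc18a3 (4.62 and 4.20 CPM) were higher in the libraries labelled AKP 2 and AKP 3 than in the others, at most 0.712 and 1.12 CPM. As a hypothesis, these libraries may hold tissue from the brainstem. The other 17 Hox genes, of which 0 reach a mean of 1 CPM in the Ptch libraries, summed to 6.13 and 5.82 CPM (85 and 79 counts) in AKP 2 and AKP 3 as against 3.003 or less (59 counts or fewer) elsewhere, and 12 brainstem markers to 174 and 146 CPM as against 88.5 or less. Tph2, 1 of these markers, was at 45.5 and 35.2 CPM as against 15.5 or less, but 6 of the 12 markers are also expressed in the Ptch libraries, and without Slc17a6, Tph2 and Slc6a4 the other 9 summed to 27.1 and 21.3 CPM as against 16.9 or less. Tph2 and Slc6a4 were also low, at 1.15 and 0.327 CPM or less, in NKP 1, NKP 2 and AKP 1, so a change of these genes with the tumour genes stays open.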
